A study of Mus musculus with 8 samples.

How the data were processed

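Per the labels' protocols, freshly isolated thymocytes were cross-linked with formaldehyde, nuclei were sonicated, and chromatin was precipitated with a rabbit antibody against Bcl11b. Libraries were sequenced on an Illumina HiSeq instrument. The labels describe 8 samples, 3 ChIP libraries of Bcl11b+/+, 3 of Bcl11b+/N440K and 2 inputs of Bcl11b+/+. The submitters' processing notes name fastp 0.20.0, Bowtie2 2.3.5, SAMtools 1.9, MACS2, bedtools, edgeR 3.38.2 and the build mm10, with no role or order; whether peaks were called per library or on pooled libraries is not given in the sources used here. Steps such as duplicate removal could cap or lower counts: the highest count of any interval was 497 or 498 in each library, in a region of chromosome 17 from 39843261 to 39848661.

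The authors deposited counts of reads in 93708 intervals of 201 bp for the 6 ChIP libraries, whole numbers with no normalization. The authors also deposited a table of CPM values for 63098 of these intervals. Each value there was the count divided by 1 constant per library. Counts came back as whole reads for 100% of the values (tolerance 0.01), the constants equalled TMM-scaled library sizes over the kept intervals, and the kept intervals were those that filterByExpr keeps. The input libraries were not used here, so enrichment over input and the alternatives that need inputs were not run. Intervals are printed with a start counted from 1. No genome sequence was used, so the planned tests of sequence words were not run.

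The main comparison used the counts of the 3 wild type and 3 N440K ChIP libraries. Intervals were filtered with filterByExpr by group, which kept 63098 and removed 30610, scaled with TMM, and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genotype was the only term. Total counts over the tested peaks ranged from 1609762 to 2400250 and scaling factors from 0.9896 to 1.0120. The common dispersion was 0.009. Counts of each pair of libraries were compared by chi-square per degree of freedom, which was 1.24 to 1.42 within and 1.55 to 1.78 between genotypes, so no library was a copy of another. In data simulated from the libraries' means and sizes over 63098 peaks, the test recovered 5 of 50 peaks changed 1.5-fold, 22 of 50 changed 2-fold, 40 of 50 changed 3-fold and 46 of 50 changed 4-fold, with 9 false calls among 122. The simulation used edgeR's own dispersions and independent peaks, so it may favour edgeR and does not cover neighbouring peaks that vary together. DESeq2 recovered 3, 11, 33 and 35 of them with 0 false calls. At this depth and number of libraries, most simulated changes of 2-fold or less were not recovered.

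Gene positions came from RefSeq on GRCm38.p6, which has the coordinates of mm10. The table gives no strand, so the planned distance to transcription start sites was replaced by the distance to gene bodies. A peak was assigned to the gene body holding it, and otherwise to the nearest within 100 kb, among 21920 protein-coding and constant-region genes; exons and introns were not told apart. The location test used peaks within 1 kb of either gene end, with 5 kb as the alternative. Gene lists numbered 14 with 206 genes. They covered T-lineage identity, early progenitors, natural killer and innate lymphoid cells, B cells, myeloid and dendritic cells, erythroid cells, thymic epithelium, regulatory T cells, maturation and egress, the Notch pathway, survival and cell cycle, NuRD and Polycomb cofactors, neurons and housekeeping. Lists were tested with limma's camera on voom values (preset correlation 0.01 and, as an alternative, estimated) and with fry.

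Named peaks followed a rule fixed before the data were examined. It took the 12 peaks with the largest fold in each direction among called peaks at or above the median signal whose libraries did not overlap between genotypes, and the 5 with the smallest p in each direction. It also took the peak with the smallest p at Bcl11b and at Bcl11a, and the best peaks of 2 genes of each list. Regions were described by the median log2 fold change over windows of 1 Mb with at least 20 tested peaks, and its interval came from 10000 bootstrap draws over peaks. Alternatives were DESeq2, limma voom, other scalings (total counts, loess offsets with a span of 0.3, the authors' factors), other filters, an adjusted p of 0.01, a test against 1.5-fold, a replicate block, leaving out each library, and leaving out X and Y. Counts recovered from the CPM table, which called 720 peaks, and fits without chromosome 12 or without unplaced sequences and the highest-count region were added after the data had been seen. So were the gene list tests with total counts, loess offsets, the replicate block and without the peaks of Bcl11b, and the Bcl11b region's median under each alternative. Software was Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0).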

Results

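Bcl11b is a zinc finger transcription factor that thymocytes need to enter and keep the T cell lineage. Its binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse thymocytes of 2 genotypes, Bcl11b+/+ and Bcl11b+/N440K, the latter carrying 1 allele with an amino acid exchange in the protein. The comparison asks which binding sites differ between them. The ChIP libraries numbered 3 per genotype. Whether the replicates came from separate animals is not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical. Counts in peaks totalled 1787899, 2661343 and 2579988 in the wild type libraries and 1997125, 1812952 and 2123877 in the N440K libraries. The 2 wild type input libraries were not analysed here, so signal is given without its background level, and differences in DNA copy number or mappability between the genotypes stay in the values.

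Bcl11b ChIP signal differed between the genotypes at 720 of 63098 tested peaks (1.14%), of which 430 were lower and 290 higher in N440K thymocytes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median change was 2.54-fold among the lower and 2.14-fold among the higher peaks. At an unadjusted p under 0.05 there were 7998 peaks. The scaling centres the log ratios near 0, so a general change in binding could not be measured. The libraries of the genotypes did not overlap at 423 of the lower and 278 of the higher peaks. Over all tested peaks this held for 17.3%, where chance gives 10%. The number of calls was tied to the tool and the libraries. DESeq2 called 60 peaks, 39 lower and 21 higher, all among the 720, and limma voom called 318, of which 146 were lower and 172 higher, so the balance turned. The excess of lower peaks was small without wild type replicate 3, with 209 lower and 195 higher, and with no filter on low counts, with 453 lower and 429 higher. Leaving out 1 library gave 408 peaks without wild type replicate 1, 469 without 2 and 404 without 3, and 289, 502 and 368 without N440K replicates 1, 2 and 3.

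**Figure D1:**
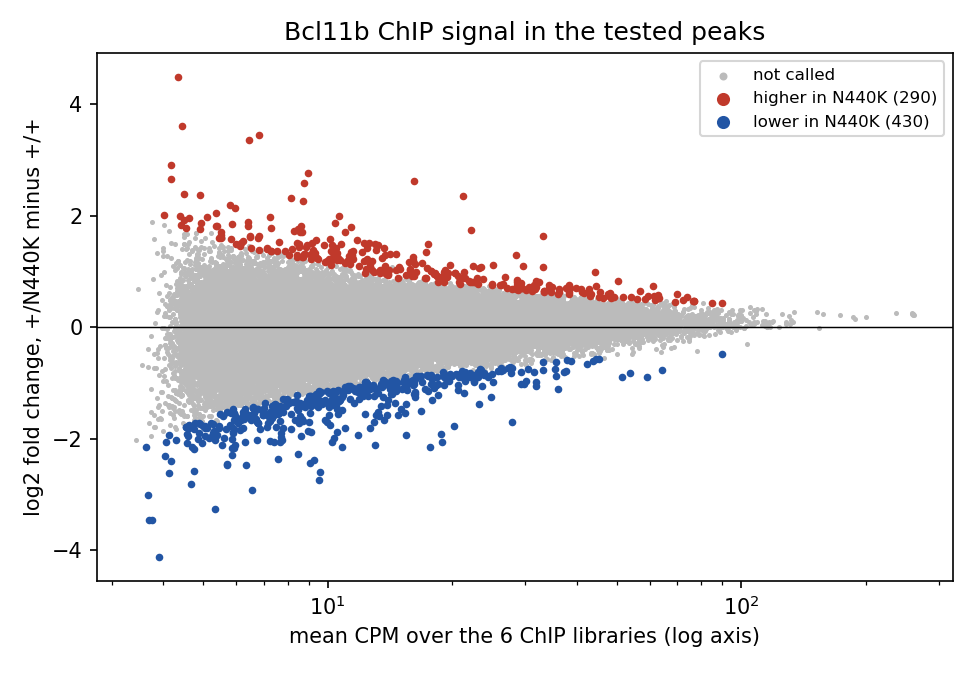
Each point is 1 of 63098 tested peaks, with its mean CPM over the 6 ChIP libraries on a log axis and its log2 fold change (N440K minus wild type) on the vertical axis. Red points are the 290 peaks called higher and blue points the 430 called lower.

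Signal fell across the Bcl11b locus itself. The peak inside the gene body at chromosome 12, 107964782 to 107964982 (mm10), had 66.8 ± 3.60 CPM in wild type and 35.9 ± 2.46 CPM in N440K thymocytes (SD, n = 3), a log2 fold change of -0.90 ± 0.14 (SE; edgeR adjusted p = 6.25e-05). The gene spans 107910403 to 108004145, and 7 of the 21 tested peaks in it were called, all lower. The change reached far beyond the gene, towards lower coordinates. From 108 to 109 Mb, 72 tested peaks had a median log2 fold change of -0.11, with 1 called higher. From 106 to 107 Mb, 22 tested peaks had a median of -0.26, with 1 called lower. Of the 85 tested peaks between 107 and 108 Mb of chromosome 12, 80 had a negative log2 fold change and 14 were called, all lower. Their median log2 fold change was -0.62 (95% bootstrap interval over peaks, -0.68 to -0.55), which is 65.1% of the wild type level. The median was -0.66, -0.60 and -0.50 in the 3 N440K libraries against the wild type mean, while each wild type library lay between -0.13 and 0.09 of the other pair. A peak 786 kb from the gene, at 107124217, had 81.4 ± 3.03 CPM in wild type and 47.3 ± 5.52 CPM in N440K (SD, n = 3; edgeR adjusted p = 0.000171); it was chosen after its values were seen. The window from 107 to 108 Mb was also singled out after the peaks had been tested. The paralog Bcl11a, whose function the study's title names, had 5 tested peaks, of which edgeR, DESeq2 and limma voom called 0, with 2 at an unadjusted edgeR p under 0.05. Its peak with the smallest p, 0.1 kb outside the gene body, had 17.7 ± 0.914 CPM in wild type and 10.9 ± 2.32 CPM in N440K (SD, n = 3; edgeR adjusted p = 0.163).

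**Figure D2:**
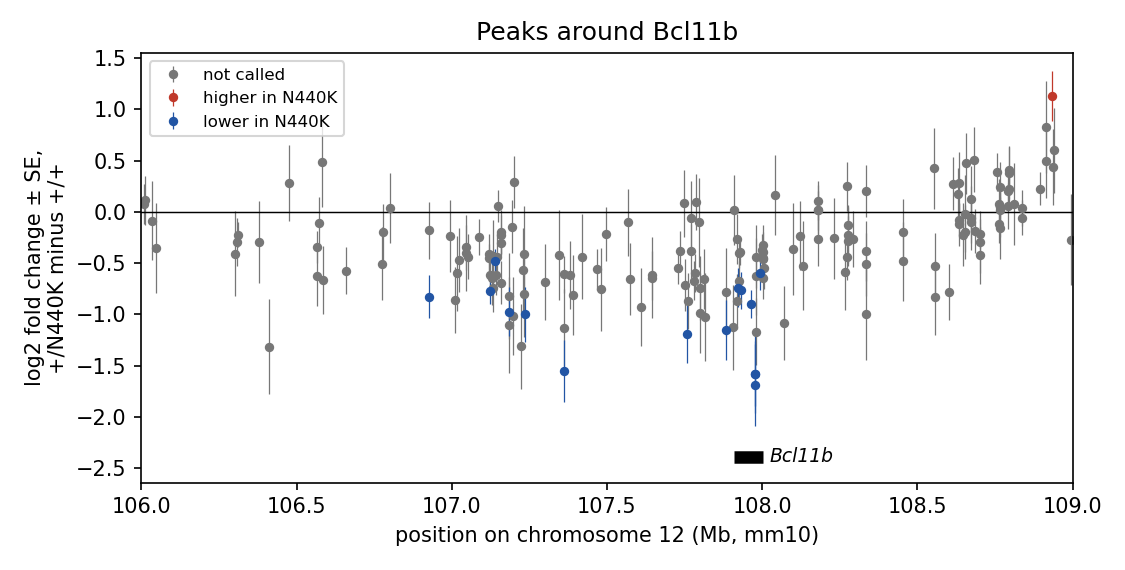
Log2 fold change (N440K minus wild type, ± SE) of each tested peak against its position between 106 and 109 Mb of chromosome 12, with the Bcl11b gene body as a black bar. Most peaks from 107 to 108 Mb lie below 0, with a median of -0.62, and the 14 called ones are all lower.

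Among the strongest losses were a peak in Gna12, which encodes a G protein alpha subunit, and one in Sorcs2, a neurotrophin co-receptor. The Gna12 peak (chromosome 5, 140784405 to 140784605) went from 42.8 ± 3.99 to 13.1 ± 0.927 CPM and the Sorcs2 peak (chromosome 5, 36213441 to 36213641) from 30.5 ± 0.664 to 7.24 ± 0.549 CPM (SD, n = 3), with edgeR adjusted p of 4.58e-08 and 5.04e-08. A peak in Fbn2, the gene of the matrix protein fibrillin-2, fell 3.76-fold, and one in Adamts2, the procollagen protease gene, fell 6.68-fold. Other large losses lay in Osbpl3 (3.41-fold), in Adcy5, an adenylate cyclase gene (3.81-fold), and in Rap1gds1 (3.02-fold). The Osbpl3 call was lost with DESeq2, and its N440K libraries were uneven, with 12.7, 12.2 and 3.12 CPM. Outside gene bodies, peaks fell 4.31-fold at 20 kb from Sox6, a transcription factor gene, 3.83-fold at 23.9 kb from Neurl1b and 3.18-fold at 0.1 kb from Bmyc. Peaks at 259.2 kb from Nuak1, the nearest gene, and at 111.5 kb from Pja1 on the X chromosome fell 4.41-fold and 3.51-fold. A further X-linked peak 23.9 kb from Fthl17a fell 3.26-fold.

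The clearest gain was in Mgat5, which encodes a branching enzyme of N-glycans. Its peak (chromosome 1, 127476754 to 127476954, inside the gene body) had 4.60 ± 1.66 CPM in wild type and 27.7 ± 5.21 CPM in N440K (SD, n = 3), a log2 fold change of 2.63 ± 0.28 (SE; edgeR adjusted p = 9.89e-09). A peak 1.5 kb from Prss51, a serine protease gene, rose from 16.2 ± 0.448 to 50.1 ± 7.11 CPM (adjusted p = 1.83e-08). The pair of peaks in Cdh13, a cadherin gene, rose 10.3-fold and 6.02-fold, from wild type means of 1.12 and 2.38 CPM. A peak at 114977673 on chromosome 12, within the immunoglobulin heavy chain locus, rose 11-fold from 1.05 CPM. Gains between 2.53-fold and 2.82-fold lay in Trappc12, Msi2 (an RNA-binding protein gene), Lgi1, Tmem132c, Pdcd1lg2 (the PD-L2 gene) and Orai2 (a calcium channel gene), and in a peak 59.8 kb from Efr3a. DESeq2 did not call the Lgi1, Tmem132c, Orai2 and Efr3a peaks, nor the Elavl4 and Padi1 peaks described next. A pair of peaks in Elavl4 and one 20.4 kb from Padi1, all on chromosome 4, also rose, by 2.82-fold to 3.35-fold, but wild type replicate 2 stood near the N440K level there. Without that library the gains at the Elavl4 peaks were 16.9-fold and 12.1-fold and the gain near Padi1 was 8.46-fold, so 1 library set the size of these changes. At the stronger Elavl4 peak the wild type libraries had 0.620, 24.7 and 3.01 CPM and the N440K libraries 33.8, 27.5 and 43.7 CPM. Of the 21 alternatives tried, the call was lost under 2 at the stronger Elavl4 peak, under 7 at the weaker Elavl4 peak and under 5 at the peak near Padi1.

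**Figure D3:**
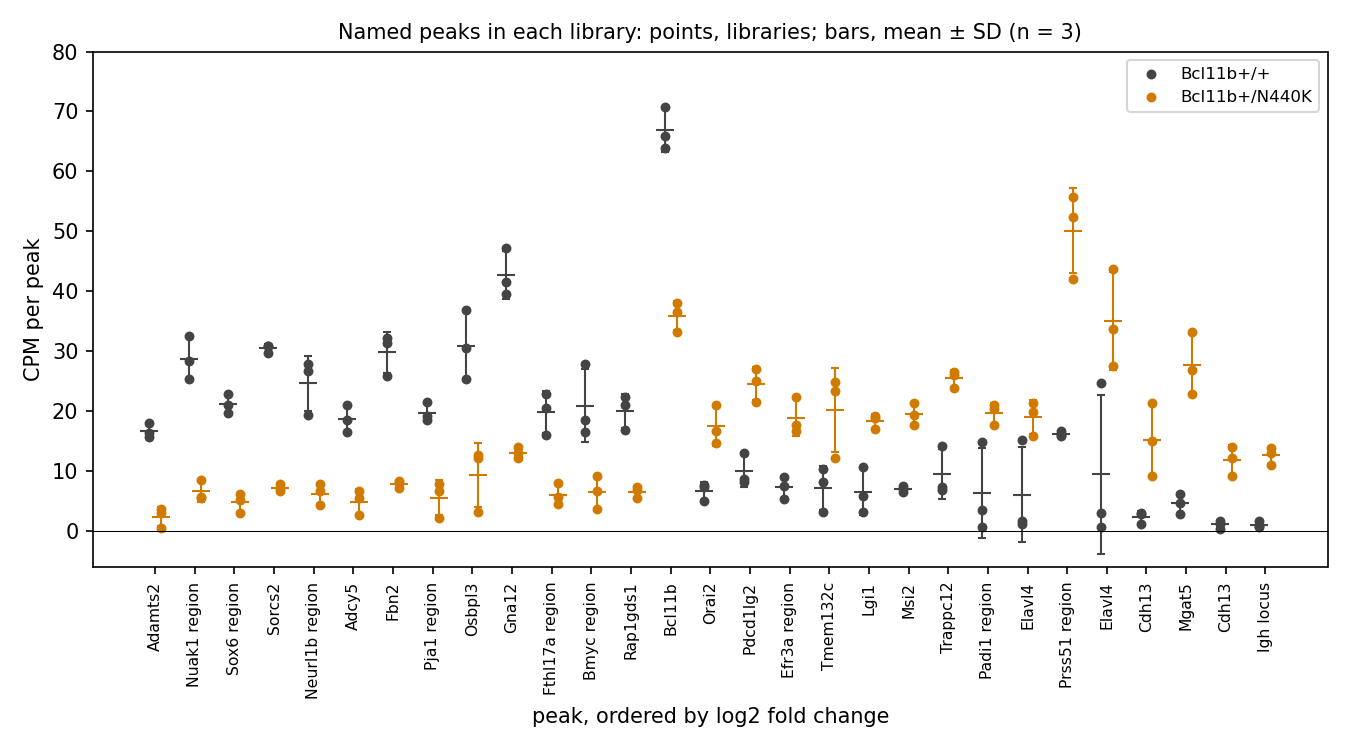
CPM of the peaks named for their fold or p, and of the Bcl11b peak, in each ChIP library (points), with mean ± SD (n = 3) as bars, wild type in grey and N440K in orange, ordered from the lowest to the highest log2 fold change. The groups do not overlap at these peaks. The wild type SD exceeds the mean at the Elavl4 and Padi1 peaks, where its bars pass below 0.

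Of the 14 gene lists fixed before the data were examined, the early progenitor genes passed the test as a group, with lower signal in N440K. The 97 tested peaks near 17 of its 18 genes had a median log2 fold change of -0.20. Camera gave adjusted p = 0.0446 with a preset correlation, and adjusted p = 0.203 with an estimated correlation. Fry gave adjusted p = 0.143. In this list edgeR called 3 peaks, all lower, and 9 when adjusted over the list alone, also all lower. DESeq2 and limma voom called 0 peaks in it. The 3 edgeR calls were a 3.31-fold loss in Lmo2 and a 3.39-fold loss in Mef2c, both regulators of early haematopoietic cells, and a 1.86-fold loss in Mycn, whose gene lies on chromosome 12. The Mef2c peak is named because the count is small, after its values were seen. The Lmo2 call was lost under 13 and the Mycn call under 10 of 20 alternatives each. The list's camera call was lost without wild type replicate 3 (adjusted p = 0.131), without N440K replicate 1 (0.163) and without N440K replicate 2 (0.242). It was also lost with total counts in peaks as library size (0.0521) and with the replicate block (0.0692).

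T-lineage identity genes had 512 tested peaks near all 32 members, of which 9 were called lower and 2 higher, or 13 and 3 when adjusted over the list alone. DESeq2 called 1 peak of this list, in Bcl11b, and limma voom called 4. Camera gave adjusted p = 0.254 for the list, 0.530 with an estimated correlation. With loess offsets the adjusted p was 0.0375, and without wild type replicate 2 it was 0.0242, both towards lower signal. Without the peaks of Bcl11b, camera with the preset correlation gave adjusted p = 0.55. The 2 settings that passed were not run without those peaks. Of the 9 lower peaks, 8 belonged to Bcl11b. The other lay 61.1 kb from Gata3, a regulator of T cell commitment, and fell 4.98-fold from 6.77 to 1.33 CPM; its call was lost under 8 of 20 alternatives. The higher ones were a 2.07-fold gain 0.2 kb from Zbtb7b, which directs the CD4 fate, and a 2.29-fold gain in Runx3, which directs the CD8 fate. Both were named after their values were seen, and DESeq2 called neither.

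Among markers of natural killer and innate lymphoid cells, 1 of 136 peaks was higher and 1 was lower. The former, 8.4 kb from Klrb1c (the NK1.1 receptor gene), rose 2.23-fold. The latter, in Zbtb16 (the gene of PLZF), fell 2.17-fold from 23.4 ± 4.61 to 10.9 ± 6.13 CPM (SD, n = 3). The 13 tested peaks assigned to Zbtb16 had a median log2 fold change of -0.73, and the 11 assigned to Klrb1c had 0.25. Of 90 peaks near regulatory T cell genes 2 were called, both higher, a 1.97-fold gain 19.5 kb from Il2ra and a 1.89-fold gain 4.7 kb from Tnfrsf18, with 3 when adjusted over the list alone. A peak 64.9 kb from Rbpj, the DNA-binding partner of Notch, rose 1.75-fold and was the 1 call among 83 peaks of the Notch pathway. A peak 5.7 kb from Cux1 was the 1 call among 127 peaks of neuronal genes and fell 2.36-fold. A peak in Notch1 did not pass, with a log2 fold change of -0.64 ± 0.18 (SE; edgeR adjusted p = 0.0639). Among the alternatives, the Rbpj call was lost under 16, the Il2ra call under 13, the Klrb1c and Tnfrsf18 calls under 9 each, the Zbtb16 call under 7 and the Cux1 call under 3. None of these lists passed camera as a group, with adjusted p = 0.782, 0.670, 0.267 and 0.254 in that order. DESeq2 called 0 peaks in each of them. Limma voom called 1 peak in the natural killer and innate lymphoid list, 0 in the regulatory T cell and Notch pathway lists and 1 in the neuronal list.

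In the 8 remaining lists edgeR, DESeq2 and limma voom called 0 of 699 peaks, with 59 at an unadjusted edgeR p under 0.05. When adjusted over the list alone, 1 thymic epithelial peak was lower. The lists covered 29 peaks of B cell, 74 of myeloid and dendritic, 6 of erythroid, 30 of thymic epithelial, 197 of maturation and egress, 191 of survival and cell cycle, 107 of NuRD and Polycomb cofactor and 65 of housekeeping genes. The camera adjusted p was 0.955, 0.267, 0.550, 0.310, 0.267, 0.267, 0.409 and 0.254 in the same order. The B cell list had a median log2 fold change of 0.03 and a mean of -0.03. Housekeeping genes passed once, without wild type replicate 2 (adjusted p = 0.0242). The 16 members that the naming rule took from these lists did not pass, 9 with a positive and 7 with a negative log2 fold change. In the B cell list a peak in Ebf1 had -1.07 ± 0.37 (SE; edgeR adjusted p = 0.155) and one in Pou2af1 had 1.05 ± 0.38 (0.184). Among survival genes a peak in Bcl2l11, the gene of the death factor Bim, had -1.12 ± 0.34 (0.0836) and one in Trp53, the p53 gene, had 0.57 ± 0.18 (0.0989). Peaks 4.6 kb from Itgam and 62.5 kb from Ywhaz had -1.20 ± 0.36 (0.0796) and 1.25 ± 0.38 (0.0891).

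Changed peaks lay away from gene ends. Within 1 kb of either end of a gene body lay 12.8% of the lower and 17.2% of the higher peaks, against 33.3% of the peaks not called (Fisher's exact test, two-sided, odds ratios 0.294 and 0.417, adjusted p = 1.79e-21 and 2.64e-09). Lower peaks were more often outside gene bodies and over 1 kb from any end (44.2% against 28.2%, odds ratio 2.01, Fisher's exact adjusted p = 7.41e-12). Higher ones were more often inside, away from the ends (50.3% against 38.3%, odds ratio 1.63, Fisher's exact adjusted p = 5.43e-05). Lower peaks inside and away from the ends made up 43.0% (odds ratio 1.21, adjusted p = 0.0626). With a distance of 5 kb from the ends, lower peaks too were more often inside (36.5% against 27.5%; odds ratio 1.52, adjusted p = 5.54e-05), and a difference between the directions was not tested. Peaks were the counted items in these tests, and neighbouring peaks are not independent.

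Weak and strong peaks moved apart slightly. The median log2 fold change was -0.08, -0.04, 0.01 and 0.06 from the weakest to the strongest quartile of mean CPM. Lower peaks made up 72.0% of the changed peaks in the weakest quartile and 38.4% in the strongest. The strongest quartile held 50.5 ± 0.391% of the counts in wild type and 52.0 ± 0.557% in N440K libraries (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allow). The difference of 0.14 between the outer quartiles came down to 0.02 with loess offsets, which remove such a trend by construction. The X chromosome held 1.49 ± 0.0137% of counts in wild type and 1.46 ± 0.0461% in N440K libraries, and the Y chromosome 0.0140 ± 0.00300% and 0.0170 ± 0.00701% (SD, n = 3; exact permutation p = 0.3 and 0.7).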

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

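The number of changed peaks (720, 290 higher and 430 lower) fell to 60 (21 and 39) with DESeq2, 318 (172 and 146) with limma voom, 327 (118 and 209) for peaks at or above the median CPM, 207 (79 and 128) at an adjusted p of 0.01 and 49 (15 and 34) against a fold of 1.5. DESeq2 had a median dispersion of 0.0575, against 0.0132 in edgeR, and recovered fewer changes in data simulated with edgeR's dispersions. The cause of the lower counts was not tested for either tool. The last 3 settings test fewer peaks or ask for more. Leaving out 1 library, which leaves fewer samples, gave 289 to 502 peaks, 116 to 219 higher and 173 to 304 lower. It gave 408, 469 and 404 without wild type replicates 1, 2 and 3, and 289, 502 and 368 without N440K replicates 1, 2 and 3. Other scalings gave 648 to 744, no filter 882, leaving out X and Y 743, and, chosen after seeing the data, leaving out chromosome 12 585 and the highest-count region with unplaced sequences 749. The difference in median log2 fold change between the outer strength quartiles moved from 0.139 to 0.0222 with loess offsets, which remove it by construction. Of 14 gene lists, 1 passed; 0 passed with an estimated correlation and with fry, and 0 to 3 without 1 library. In settings chosen after seeing the data, 0 passed with total counts and with the replicate block, and 2 with loess offsets. The cause was not tested. Of 38 named called peaks, 21 kept their call with DESeq2 and 31 with limma voom, and none changed direction. The median of the Bcl11b region stayed between -0.68 and -0.57 in every setting that held its peaks. With replicate number as a block, 753 peaks were called, and 674 with loess offsets as well. Whether the numbers pair the libraries was not settled. Deviations of same-numbered libraries correlated at -0.004, 0.028 and 0.058, and those of the other pairs at -0.047 to 0.017. N440K replicates 2 and 3 correlated best with their own number but replicate 1 with wild type replicate 2. Alternatives that need input counts or a genome sequence were not run. At this depth and number of libraries, 5 of 50 simulated changes of 1.5-fold were recovered.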

Other observations

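The tests of single libraries, strength on chromosome 12 and loess offsets were set before their results were seen; the other tests below were chosen only afterwards. Changed peaks often stood side by side and moved together. Of 147 neighbouring pairs of changed peaks within 50 kb, 143 changed in the same direction, against a median of 76 when directions were shuffled (permutation p = 0.0001, the smallest 10000 shuffles can give). Random peaks of the same strength formed a median of 38 such pairs. Some changed peaks lay very close together, as in Cacna1c, where 3 called peaks lay within 1.02 kb. Close pairs may be 1 site, which would move in 1 direction, and the count was not repeated without them. In 30 runs of at least 3 changed peaks, 18 were all lower and 9 all higher. The medians of such runs cover the called peaks, and the values of the other tested peaks in their spans are given beside them. In the HoxA cluster, patterning genes active in early haematopoietic cells, 3 of 6 tested peaks were lower, with a median of 3.61-fold, and the other 3 had a median log2 fold change of -1.09. In Dysf, a membrane repair gene, 5 of 7 were lower (3.19-fold), the other 2 at -0.69. In Pip5k1b 6 of 22 were lower (2.34-fold), the other 16 at -0.61. In Stk3, a Hippo pathway kinase gene, 6 of 10 were higher (2.20-fold), the other 4 at 0.78, and in Stau2 4 of 7 (2.79-fold), the other 3 at 1.03. In Cdh13 (8.06-fold) and near Prss51 and Msra (2.94-fold) all 4 tested peaks of the span were higher.

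The differences between antigen receptor loci were not tested. The 60 tested peaks of the immunoglobulin heavy chain locus had a median log2 fold change of -0.51 (95% bootstrap interval -0.63 to -0.11), with 10 called lower and 2 higher; the window medians were -0.81 from 115 to 116 Mb and -0.015 from 113 to 114 Mb. The 66 peaks of the T cell receptor alpha and delta locus had a median of -0.05 (-0.22 to -0.01) and the 34 of the beta locus -0.01 (-0.06 to 0.08). The gamma locus had 4 peaks with a median of 0.54 (interval bounds -0.0034 and 0.88), and the immunoglobulin kappa locus 3 peaks with a median of -0.13 (-0.38 to 0.42).

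Signal across 107 to 108 Mb of chromosome 12 was lower at 80 of 85 peaks, the third lowest median among 1090 windows of 1 Mb. Loss of 1 of 2 copies of the whole region in all cells would put the median near -1, and its interval ended at -0.682. That argues against such a loss, but the interval covers the spread over peaks only. A loss of part of the region or in part of the cells was not tested. Abundance-dependent normalization is also argued against, as the median stayed at -0.628 with loess offsets. The 483 peaks of the other T-lineage genes had a median of -0.0179 (interval -0.0612 to 0.00811). The scaling centres the log ratios near 0, so the share of T-lineage cells itself could not be measured. The scaling acts on both sets of peaks alike, however, and a lower share would lower both. The gap between the sets therefore argues against a lower share as the source of the drop in this region. What lowers the signal stays open; Bcl11b occupancy apart from chromatin accessibility was not tested, and input libraries were not used here. With 6 libraries there are 10 splits of 3 against 3, too few for a share under 0.05; the real split had a median of 0.619 in size, 1 of 10 that large, and the highest other 0.311.

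Outside that window, chromosome 12 still held 66 changed among 2475 tested peaks (2.67%), against 1.07% on the other autosomes (Fisher's exact p = 1.77e-10). Peaks were the counted items in the Fisher's exact tests here, and neighbouring changed peaks moved together, so these p-values may be too small. A difference in peak strength is argued against, since the count was 2.51 times that expected from the strength of the peaks. Lower copy number at the distal heavy chain locus may contribute but was not settled. The median log2 fold change of the 24 peaks between 115 and 116 Mb was -0.81, with an interval from -1.12 to -0.541 that holds -1. The same interval also holds the -0.619 of the Bcl11b region, so it does not separate the 2 cases. Of these peaks 8 were called lower and 1 higher. A haplotype linked to the mutated allele cannot be told apart from other sources, because the excess within 10 Mb of Bcl11b (odds ratio 1.86, Fisher's exact p = 0.0143) came to 1.17 (exact p = 0.647) without the heavy chain locus, and chromosome 12 beyond 10 Mb also exceeded the other autosomes (2.14%, odds ratio 2.03, exact p = 0.000145). Peaks that deviated in single libraries also grouped. Of 59 neighbouring pairs, 20 deviated in the same library and direction, against a shuffled median of 7 (permutation p = 0.0001, the smallest possible). Some of these pairs were intervals within 1 kb of each other. Examples were 60601578 and 60601803 in Dapk1 on chromosome 13, both low in N440K replicate 3. Such pairs may be 1 site, and distances were not examined. Segregating background variation or copy number is a candidate source for some runs but was not tested.

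The rise of fold change with peak strength could come from ChIP enrichment of single libraries. It differed by up to 0.109 between libraries of 1 genotype, while pairs across genotypes differed by 0.0464 to 0.226, with a median of 0.104. The 0.109 came from N440K replicates 2 and 3, and the next largest within a genotype was 0.062, from wild type replicates 2 and 3. In every pair across genotypes the trend was higher in the N440K library. These values do not separate enrichment of single libraries from a difference between the genotypes.

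For the 720 changed peaks, 1 of the 10 splits of the 6 libraries, the real one, gave as many, and the highest other gave 14; 10 splits are too few for a share under 0.05. For the 1 list that passed, 3 of the 10 splits gave as many, the highest other 2.

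At a peak 12.8 kb from St6galnac1, named after its values were seen, N440K replicate 1 deviated by -3.42 on the log2 scale from the mean of the other N440K libraries.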
